A study of Mus musculus with 7 samples.

How the data were processed

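RNA was measured in 7 mouse liver libraries, 3 labelled MDL-800 and 4 labelled control. Per the labels' protocols, livers were lysed directly, cDNA was made and amplified with a low-input SMARTer kit, sheared, and built into libraries with an NEBNext kit. That chemistry does not mark strand, so antisense and overlapping genes share reads. The authors deposited 1 table of FPKM values per gene, with gene identifiers, coordinates and lengths. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.1.0 and Cufflinks 2.2.1 were used with build mm9. Which tool counted the reads is not given in the sources used here. The coordinates of the table are those of GRCm38: 53842 of the 54495 gene identifiers shared with GENCODE M21 have the same chromosome and start, so coordinates are given as GRCm38.

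In each library, the deposited FPKM times gene length was a whole multiple of 1 step, which recovered whole reads per gene (100% of nonzero values within 0.01 of a whole number). The ratio of summed reads to the deposited denominator ran from 0.995 in control 2 to 1.28 in MDL-800 2, so the denominator was not the sum of these reads. Recovered reads numbered 17600066 to 19920469 per library. A gene at 0 reads was given a limit of 3 reads. PCR duplicates were not marked by molecular identifiers, so such limits cover counting error only.

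Values were tested as log2(FPKM + 1) of the deposited table, without rescaling, for genes with a mean of at least 1 FPKM. Fold changes on this scale understate the change of genes with low values. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested with limma camera at a preset correlation of 0.01, over lists with at least 5 tested members: 52 of 57 lists, for which 1030 of 1038 symbols were found. Alternatives to the list test were an estimated correlation, fry, and an exact permutation of the per-library list mean over 35 assignments. Sirt6 was also tested by exact permutation.

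The groups, the main tests, the lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the smallest p in each direction where none passed, the sirtuins, up to 4 members of each list that passed with the smallest p, and the 2 members with the highest mean of passing cell type, quality and sex lists. Orm2, Lcn2, Cyp4a12a, Sult2a1, Hsd3b5, Cyp2a4 and the sex chromosome transcripts were chosen after their values were seen. Some genes that the rule takes are not reported here. Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, median scaling, a replicate block, array weights, a robust prior and leaving out each library. A term for Y-linked transcripts, the 5 Y-negative libraries alone, limma voom on recovered reads, summed reads as the denominator and the permutation of list means were chosen after seeing the data.

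The procedure was tested on simulated data, in which 10 simulated sets kept the real means, denominators and spread over 54532 genes, with 200 genes changed. The gene test called 6.22% of 1.5-fold, 36.7% of 2-fold and 75.2% of 4-fold changes, and 0.053% of unchanged genes. A list shifted by -0.6 on the log2 scale was called in 10 of 10 sets, and 2 of 510 tests of other lists were called. The simulated genes were drawn independently, so the correlation between genes of the real libraries was not part of that test. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.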

Results

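Liver RNA from old C57BL/6 mice was sequenced in 7 libraries, 3 from animals given a standard diet following MDL-800 supplementation and 4 from control animals given a standard diet. MDL-800 is a small-molecule activator of SIRT6, an NAD-dependent deacetylase. The comparison addresses how the liver transcriptome of treated animals differed from that of controls. Whole reads per gene recovered from the deposited FPKM values summed to 17600066 to 19920469 per library, with a mean of 19134000 ± 784360 (SD, n = 3) for MDL-800 and 18284000 ± 758910 (SD, n = 4) for control. Of 54532 genes listed, 27557 were at 0 in all 7 libraries, and 11394 had a mean of at least 1 FPKM in the deposited table and were tested. Each library came from liver of the stated strain, and nothing in the labels says whether each came from a separate animal, so p-values measure the spread between these libraries.

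The 7 libraries differed in transcripts of the sex chromosomes, and the labels used here give no sex. Control 1 and MDL-800 2 held 2173 and 3514 reads from the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, and 3 reads each from Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254, GRCm38). The other 5 libraries held 0 reads of these Y-linked genes and are called Y-negative here. Xist reached 49.98 to 63.51 FPKM in the deposited values of control 2, control 4, MDL-800 1 and MDL-800 3. Control 3 had 0 reads of Xist, which allows up to 0.0118 FPKM on the deposited scale when 3 reads are taken as the limit for counting error. The first principal component held 49.6% of the variance of the tested genes and separated control 1 and MDL-800 2 from the other libraries. The male-biased liver gene Cyp4a12a stood at 66.7 and 82.9 FPKM in control 1 and MDL-800 2 and at most 0.0956 FPKM elsewhere in the deposited values. The female-biased Sult2a1 was at 0 in those 2 libraries and at 519.7 to 1118 FPKM in the other 5 as deposited.

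**Figure D1:**
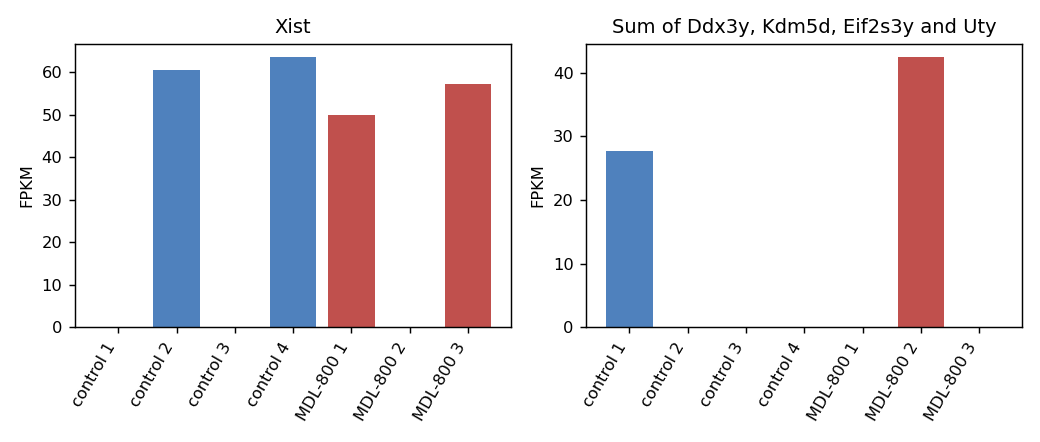
Bars show deposited FPKM per library for Xist (left) and for the sum of 4 Y-linked genes (right), with control in blue and MDL-800 in red. Control 1 and MDL-800 2 held the Y-linked signal (27.8 and 42.4 FPKM), and control 3 held neither signal.

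No gene passed the limma test between MDL-800 and control livers at an adjusted p under 0.05. The genes closest to the threshold in the higher direction were the long noncoding RNA genes Gm34654 and Gm36041 and Cyp46a1, which encodes cholesterol 24-hydroxylase. In the lower direction they were Socs3, a feedback inhibitor of cytokine signalling, the small nucleolar RNA gene Gm22200 and Cxcl1, a neutrophil-attracting chemokine. The lowest adjusted p of limma was 0.333, 553 of 11394 genes had an unadjusted p under 0.05 (368 higher and 185 lower in MDL-800), and 570 would be given by chance. With limma voom on recovered reads 0 genes passed as well, and 541 had an unadjusted p under 0.05. The unadjusted count ran from 274 without MDL-800 3 to 948 without control 1 when a library was left out, and was 946 with array weights and 828 with a term for Y-linked transcripts. The balance of directions depended on the scaling: 354 of 660 were higher with each library scaled to its median, and 630 of 776 with summed reads as the denominator. Without control 2, 247 of 511 were higher, without MDL-800 2, 219 of 406, and with array weights 527 of 946. The groups did not overlap for 735 genes (459 higher, 276 lower), and chance gives 5.71% of genes, or 651. Without control 1, Cyp46a1 passed (adjusted p = 0.0293), and without MDL-800 1, Gm34654 passed (adjusted p = 0.0308). Their adjusted p over all alternatives ranged from 0.0293 to 0.999 for Cyp46a1 and from 0.0308 to 0.999 for Gm34654.

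The genes named first did not pass, and their values were as follows. Gm34654 (chromosome 9, 77807036 to 77809793, GRCm38) was at 6.72 ± 2.73 FPKM (SD, n = 3) in MDL-800 and 0.369 ± 0.194 FPKM (SD, n = 4) in control, as deposited, a log2 fold change of 2.43 with a standard error of 0.27, or 3.85 with a pseudocount of 0.1 and 4.01 with voom. Gm36041 (chromosome 10, 122386892 to 122435033), which overlaps a gene on the opposite strand, had a log2 fold change of 0.81 with a standard error of 0.10. Cyp46a1 (chromosome 12, 108334381 to 108362234) was at 3.88 ± 0.245 FPKM (SD, n = 3) against 0.683 ± 0.540 FPKM (SD, n = 4) in the deposited values, a log2 fold change of 1.58, or 2.55 with a pseudocount of 0.1 and 2.78 with voom. Lgals1, which encodes galectin-1, was at 84.6 ± 12.3 against 34.8 ± 9.22 FPKM, and Dsp, which encodes the junction protein desmoplakin, at 9.06 ± 0.867 against 5.60 ± 0.361 FPKM, as deposited. The other higher genes by p were Carnmt1, Siae, Zfp955b, Pgrmc2 and Snrpert, with log2 fold changes of 0.83, 0.64, 0.44, 0.62 and 0.85. Dsp and Siae overlap genes on the opposite strand, and Snrpert is a processed pseudogene inside Rnf24, so their reads are uncertain.

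Socs3 (chromosome 11, 117966079 to 117970047) was at 3.41 ± 0.612 FPKM (SD, n = 3) in MDL-800 and 7.59 ± 0.755 FPKM (SD, n = 4) in control as deposited, a log2 fold change of -0.97 with a standard error of 0.13. Cxcl1 (chromosome 5, 90891241 to 90893115) was at 9.47 ± 2.95 against 23.8 ± 3.88 FPKM as deposited, with a log2 fold change of -1.28. Ifitm2, an interferon-induced transmembrane protein gene, was at 183.4 ± 10.4 against 354 ± 95.4 FPKM as deposited, and Isyna1, which encodes inositol-3-phosphate synthase, at 2.95 ± 1.05 against 8.44 ± 2.88 FPKM. Gm22200 was listed at 0 in the 3 MDL-800 libraries and rested on 1 to 4 reads in each control library, and it lies inside Hspa9, so no fold is given. The remaining lower genes by p were Atp11a, Sema6b, Gm30301, Snord72 and Alg8, with log2 fold changes of -0.79, -0.46, -0.74, -1.20 and -0.38. Snord72 lies inside Rpl37 and its reads cannot be told from those of the host gene.

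Sirt6 (chromosome 10, 81621785 to 81627797, GRCm38), the transcript of the enzyme that MDL-800 activates, was at 1.65 ± 0.301 FPKM (SD, n = 3) in MDL-800 and 1.73 ± 0.110 FPKM (SD, n = 4) in control as deposited. The log2 fold change was -0.05 (95% interval from -0.31 to 0.22), with an exact two-sided permutation p of 0.629 over 35 assignments. Its standard error was 0.11, and the value was 0.011 within the 5 Y-negative libraries, a change of sign. Among the other sirtuins, Sirt3, the main mitochondrial deacetylase, had the highest log2 fold change, 0.40 with a standard error of 0.30. The Sirt3 value was 0.61 without control 1, 0.24 without control 2, 0.16 without MDL-800 2 and 0.26 with array weights, and Sirt3 was higher in the 2 libraries with Y-linked reads than in the other 5 (limma adjusted p = 0.0447, log2 difference 0.79). Sirt7 had -0.27 with a standard error of 0.16, and was at -0.41 without MDL-800 2 and -0.14 without MDL-800 3. Sirt5 had 0.16, and 0.26 without control 1 or 0.25 with voom. Sirt1, Sirt2 and Sirt4 were at 0.01, -0.04 and 0.03 and each changed sign when single libraries were left out, as Sirt1 and Sirt4 did with each library scaled to its median. Sirt1, Sirt2, Sirt3 and Sirt7 overlap other genes.

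Among 52 gene lists fixed before the data were examined, acute phase proteins, mostly plasma proteins that hepatocytes secrete in inflammation, showed the lowest adjusted p. The list also held Mt1, Mt2 and Steap4, which do not encode secreted plasma proteins (log2 fold changes of -1.77, -2.11 and -0.44). Of 24 measured members, 23 had a log2 fold change below 0, with a median of -0.66. The per-library mean of the list on the log2 scale was 7.80 ± 0.28 (SD, n = 3) in MDL-800 and 8.65 ± 0.40 (SD, n = 4) in control. The list passed limma camera with a preset correlation of 0.01 (adjusted p = 3.96e-11), and its adjusted p was 0.648 with an estimated correlation. The exact permutation p of the list mean was 0.0571, where the smallest that 35 assignments can give is 0.0286. No member passed over all genes tested or when adjusted over the list alone. Saa1, serum amyloid A, was at 67.3 ± 17.9 FPKM (SD, n = 3) against 149.2 ± 51.0 FPKM (SD, n = 4) as deposited, and Orm1, orosomucoid, at 1112 ± 224 against 2711 ± 1359 FPKM. Itih3 and Orm3 had log2 fold changes of -0.57 and -1.52. Orm1, Orm2 and Orm3 are close paralogs, as are Saa1 and its list neighbour Saa2, so the reads of these genes are uncertain. Control 4 had 2392 FPKM of Orm2 and 426.3 FPKM of Lcn2 in the deposited values, the highest of the 7 libraries. Within the 5 Y-negative libraries the list median was -0.63 (camera with the preset correlation, adjusted p = 1.84e-10). These were MDL-800 1 and MDL-800 3 against control 2, control 3 and control 4. That p treats the genes as nearly independent, and no estimated correlation or permutation was run there. The only Y-positive pair, 1 library per group, was at 7.56 in MDL-800 2 and 8.15 in control 1, with no test.

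Fatty acid oxidation genes and targets of the nuclear receptor PPARa had a median above 0 in MDL-800 against control. So did the TCA cycle, oxidative phosphorylation and lipid synthesis lists, but their per-library means overlapped between groups. On the TCA cycle list control 1 (5.314) lay above MDL-800 1 (5.293), and on oxidative phosphorylation control 1 (6.911) above MDL-800 1 and MDL-800 3 (6.677 and 6.673). On lipid synthesis control 3 (5.642) lay above MDL-800 1 and MDL-800 2 (4.877 and 5.451). The exact permutation p was 0.314 for oxidative phosphorylation and for lipid synthesis. In the fatty acid oxidation list 31 of 33 members were above 0, with a median log2 fold change of 0.43 (camera adjusted p = 7.88e-08, adjusted p = 0.982 with an estimated correlation). The exact permutation p of its per-library mean was 0.0571. Within the 5 Y-negative libraries the median was 0.53 (camera with the preset correlation, adjusted p = 5.35e-10). That p treats the genes as nearly independent, and no estimated correlation or permutation was run there. Ehhadh, a peroxisomal beta-oxidation enzyme, was at 149.9 ± 29.9 FPKM (SD, n = 3) against 92.5 ± 12.9 FPKM (SD, n = 4) as deposited, and Cpt1a, which carries out the rate-limiting step of mitochondrial entry, at 96.3 ± 11.1 against 63.1 ± 15.3 FPKM. Vnn1 and Ppara had log2 fold changes of 1.06 and 1.08. In the TCA cycle list 17 of 18 members were above 0, with a median of 0.27 (camera adjusted p = 0.000393, adjusted p = 0.982 with an estimated correlation). Without control 2 the TCA cycle median was 0.17. Dlat, Cs and Suclg2 had log2 fold changes of 0.63, 0.29 and 0.32. In the oxidative phosphorylation list 34 of 35 members were above 0, with a median of 0.17 (camera adjusted p = 0.0012, 0.982 as the adjusted p with an estimated correlation). Sdhd, Ndufs1, Atp5b and Sdha had log2 fold changes of 0.43, 0.32, 0.37 and 0.44. The oxidative phosphorylation call ended without control 2 (median 0.06) and without MDL-800 2 (median 0.07), with an adjusted p up to 0.2. Its median was 0.28 without control 1 and 0.10 with array weights. In the list of fatty acid and triglyceride synthesis 18 of 21 members were above 0, with a median of 0.29 (camera adjusted p = 0.00214, 0.982 as the adjusted p with an estimated correlation). Elovl5, Elovl6, Gpam and Scd1, enzymes of fatty acid elongation, glycerolipid assembly and desaturation, had log2 fold changes of 1.03, 0.93, 1.12 and 1.09. Scd1 was at 618.8 FPKM in MDL-800 1, within the control range of 493.1 to 844.3 FPKM, and at 2123 and 1888 FPKM in MDL-800 2 and MDL-800 3 as deposited, and its log2 fold change was 1.66 without MDL-800 1 and 0.64 in the Y-negative libraries. That call ended without control 1, without MDL-800 3 and within the 5 Y-negative libraries, where the median was 0.16 (adjusted p = 0.206). The median of that list was 0.46 without control 3, 0.65 without MDL-800 1 and 0.19 without MDL-800 2. No member of these 4 lists passed over all genes tested or when adjusted over the list alone.

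**Figure D2:**
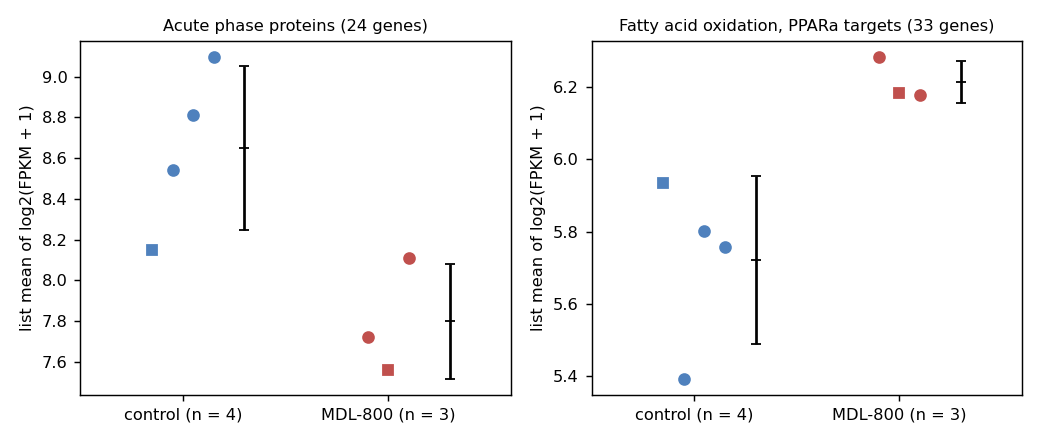
Points show the mean of log2(FPKM + 1) of the deposited values over list members in each library, squares mark the 2 libraries with Y-linked reads, and the bar at the side of each group gives the mean and SD. The acute phase list averaged 7.80 in MDL-800 and 8.65 in control, and the fatty acid oxidation list 6.21 and 5.72.

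Immediate early genes, NF-kB targets, complement and coagulation genes and antigen presentation genes had medians below 0 in MDL-800 against control. These medians were smaller in size than that of acute phase proteins, and those of NF-kB targets and antigen presentation changed sign under some alternatives. Interferon-stimulated genes did not pass (median -0.03, 11 members above and 13 below 0, adjusted p = 0.477). Macrophage and Kupffer cell markers, which did not pass, had a median of -0.36 with 15 of 18 members below 0 (adjusted p = 0.102), and monocyte markers -0.32 with 11 of 13 below 0 (adjusted p = 0.165). The log2 mean of the macrophage markers was highest in control 2 (6.21) and lowest in MDL-800 2 (3.77), as were those of NF-kB targets (3.36 and 1.69) and antigen presentation genes (6.05 and 4.31). Control 1, the other library with Y-linked reads, was next lowest in each of these lists (3.80, 1.96 and 5.195). Of 16 immediate early genes, which respond within minutes to stress or handling, 13 were below 0, with a median of -0.19 (camera adjusted p = 0.00214, 0.982 as the adjusted p with an estimated correlation). Socs3 alone passed limma when adjusted over the list alone, which does not correct for the number of lists. Its limma adjusted p over all genes was 0.467. Ier2, Junb, Egr1 and Jund had log2 fold changes of -0.63, -0.53, -0.94 and -0.16, and control 2 held the highest Egr1 value (18.3 FPKM as deposited), without which Egr1 was at -0.43. Egr1 was at -0.57 without MDL-800 2 and -1.43 without MDL-800 3, and Junb at -0.29 without MDL-800 1. Jund was at -0.26 without control 2, -0.32 without MDL-800 3 and -0.044 without MDL-800 2, and turned to 0.0085 in the Y-negative libraries. The call ended without control 2 (median -0.05, adjusted p = 0.272). The immediate early median was -0.44 without control 1, -0.30 without control 3, -0.09 without MDL-800 1, -0.39 without MDL-800 3 and -0.45 in the Y-negative libraries. Of 19 targets of the inflammatory regulator NF-kB, 15 were below 0, with a median of -0.13 (camera adjusted p = 0.038, 0.982 as the adjusted p with an estimated correlation). Cxcl1 alone passed when adjusted over the list alone, with the same limit (limma adjusted p over all genes = 0.95). Nfkbiz, Nfkbia and Ccl4 had log2 fold changes of -1.01, -0.27 and -0.66. Nfkbia was at -0.45 without control 3. Ccl4 was at -0.20 without control 2 or without MDL-800 2, -1.11 without control 1, -1.12 without MDL-800 1 and -0.35 with array weights, and at -1.07 with a pseudocount of 0.1 and -1.20 with voom. This call ended without control 2, without control 4 or without MDL-800 2, and within the 5 Y-negative libraries (adjusted p = 0.293), and the median turned to 0.11 without control 2, to 0.07 without MDL-800 2 and to 0.08 with array weights. It also ended with quantile normalization, median scaling, no filter and a term for Y-linked transcripts, and the median was -0.29 without control 1, -0.205 without control 3, -0.25 without MDL-800 1 and -0.37 without MDL-800 3. Of 25 complement and coagulation genes, 20 were below 0, with a median of -0.11 (camera adjusted p = 0.00848, 0.982 as the adjusted p with an estimated correlation). Kng1 and F7 had log2 fold changes of -0.49 and -0.74, and Cfb had 0.32. F7 was highest in control 3 (247.5 FPKM as deposited) and was at -0.39 without it, and Cfb was at 0.21 without control 4. The complement call ended without control 1, without MDL-800 1 and without a filter on low values (adjusted p up to 0.0753). Its median was -0.22 without control 2 or with array weights, -0.23 without MDL-800 2, -0.04 without MDL-800 3 and -0.06 with quantile normalization. Of 14 antigen presentation genes, 13 were below 0, with a median of -0.35 (camera adjusted p = 0.0423, 0.982 as the adjusted p with an estimated correlation). Nlrc5, Psmb9, Psmb8 and Tap2 had log2 fold changes of -0.29, -0.31, -0.38 and -0.23, and Psmb9, Psmb8 and Tap2 turned above 0 without MDL-800 2. With the limma term for Y-linked reads, Psmb8 was lower in the libraries that held them (log2 difference -0.99, adjusted p = 0.0363). Nlrc5 was at -0.14 without control 4, -0.16 without MDL-800 2 and -0.17 in the Y-negative libraries, where Psmb9, Psmb8 and Tap2 were at -0.10, -0.19 and -0.086. Array weights gave the same 3 genes -0.13, -0.20 and -0.087. Psmb9 and Tap2 were at -0.49 and -0.38 without MDL-800 3, Tap2 at -0.15 without control 2, and Psmb8 at -0.59 without control 1, -0.60 without MDL-800 1 and -0.23 without control 4. The antigen presentation call ended without control 2, without control 4 or without MDL-800 2, and with quantile normalization, median scaling or no filter. The antigen presentation median turned to 0.19 without MDL-800 2, to 0.013 with array weights and to 0.06 within the 5 Y-negative libraries (adjusted p = 0.936). It was -0.18 without control 2, -0.23 without control 4, -0.52 without MDL-800 1 and -0.53 without MDL-800 3.

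Of the marker lists of other cell types, those of B and plasma cells and of endothelial cells passed camera with the preset correlation, and single libraries stood apart in both. All 15 B and plasma cell markers measured were below 0, with a median of -0.60 (camera adjusted p = 0.00335, 0.982 as the adjusted p with an estimated correlation). Cd79b was at 23.4 FPKM in control 4 and between 0.944 and 8.98 FPKM in the other 6 libraries as deposited. Igkc, the immunoglobulin kappa constant region, was at 1206 FPKM in control 3 and 858.8 FPKM in MDL-800 1 as deposited. Xbp1, which hepatocytes also express, Blk and Ighm had log2 fold changes of -0.47, -0.56 and -1.02, Blk was at -0.14 without control 4, and Ighm was at -0.13 without MDL-800 2. Blk was at -0.96 with a pseudocount of 0.1 and -0.97 with voom, and Ighm at -2.01 without MDL-800 1, -0.57 without control 3, -0.55 with array weights and -0.41 in the Y-negative libraries. The B cell median was -1.05 without control 2 or without MDL-800 1, -0.36 without control 3, -0.335 without control 4 and -0.20 without MDL-800 2. The B cell call ended without control 3 (adjusted p = 0.0814), without control 4 (adjusted p = 0.0684), without MDL-800 2, and within the 5 Y-negative libraries (adjusted p = 0.0674). Of 17 endothelial markers, 15 were above 0, with a median of 0.24 (camera adjusted p = 0.0406, 0.982 as the adjusted p with an estimated correlation). Clec4g, a sinusoidal endothelial lectin, was at 2.40 FPKM in control 4 and between 11.7 and 14.7 FPKM in the other 6 libraries as deposited. Bmp2, Oit3, Fcgr2b, Kdr and Eng had log2 fold changes of 0.69, 0.49, 0.25, 0.33 and 0.24, and of 0.38, 0.16, 0.12, 0.11 and -0.035 without control 4. Eng was at 0.40 without control 3 or without MDL-800 2, 0.14 without MDL-800 3, 0.44 in the Y-negative libraries and 0.445 with array weights. Bmp2 and Kdr were at 1.05 and 0.52 with a pseudocount of 0.1 and at 1.08 and 0.54 with voom. The endothelial median was 0.08 without control 4 (adjusted p = 0.447), and the call also ended without control 1, without MDL-800 1, without MDL-800 3 and with summed reads as the denominator. Stellate cell and myofibroblast markers, which did not pass, had a median of 0.21 with 13 of 15 members above 0 (camera adjusted p = 0.238). Control 4 had the lowest log2 mean of both the endothelial (1.33) and the stellate list (1.56). Of 17 major urinary protein genes, 12 were below 0, with a median of -0.97 (camera adjusted p = 0.0406, 0.982 as the adjusted p with an estimated correlation). These genes are near-identical copies whose reads are uncertain, and Mup17 (1538 FPKM), Mup15 (1073 FPKM), Mup18 (144.7 FPKM) and Mup8 (6.38 FPKM) were highest in control 3 as deposited. Mup3 and Mup7, the members with the highest mean, were highest in control 1 and MDL-800 2. The log2 mean of the list was 5.35 in control 3, 5.70 and 7.13 in the 2 libraries with Y-linked reads and 1.04 to 2.88 in the other 4. The call on major urinary proteins ended without control 1, without control 3 (adjusted p = 0.112), without MDL-800 1 and without MDL-800 3, and with quantile normalization, median scaling, a pseudocount of 0.1, other filters or voom. Its median ran from -2.40 without MDL-800 2 to -0.26 without MDL-800 1, and was -0.48 without control 1, -0.50 without control 3, -1.57 without control 4 and -0.52 without MDL-800 3.

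**Figure D3:**
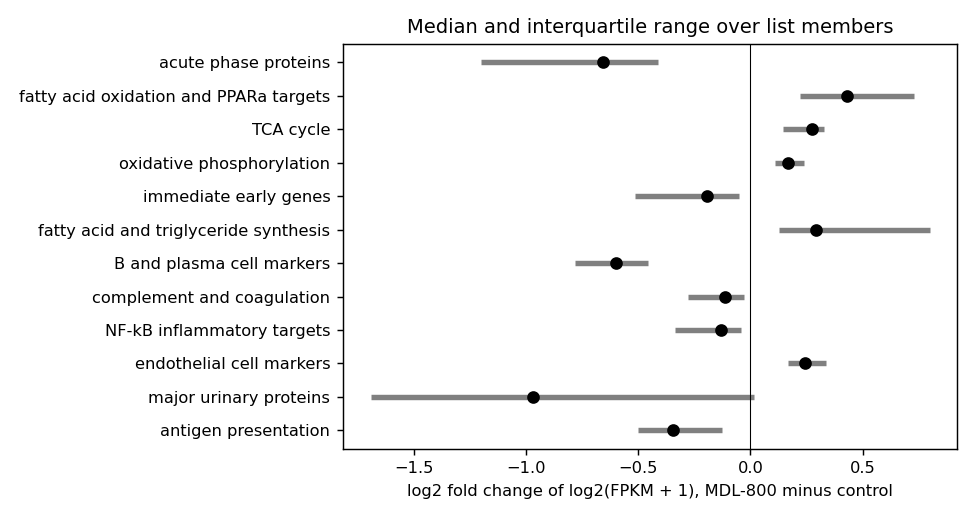
Points give the median log2 fold change (MDL-800 minus control) over the members of each of the 12 lists that passed camera with the preset correlation, and bars the interquartile range. The medians run from -0.97 for major urinary proteins to 0.43 for fatty acid oxidation.

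In all, 12 of 52 lists passed camera with the preset correlation, 5 higher and 7 lower in MDL-800, and 9 passed with each library scaled to its median or quantile normalized, 5 higher and 4 lower. Without MDL-800 2, 19 passed, 11 higher and 8 lower, while without control 1 the split was 3 higher and 13 lower, without MDL-800 3 it was 3 and 12, and with summed reads as the denominator 4 and 10. With an estimated correlation 0 of the 52 passed, as with fry (lowest adjusted p = 0.828) and with the adjusted permutation of list means. The unadjusted exact permutation p was 0.0571 for acute phase proteins and for fatty acid oxidation, and 0.0857 for the TCA cycle. For the rest of the lists that passed camera it ran from 0.314 to 0.629. Genes described as repressed by SIRT6 had a median log2 fold change of -0.04 over 26 members (adjusted p = 0.908), and their mean was 0.07. DNA repair genes had a median of 0.05 over 22 members (adjusted p = 0.683). Their per-library mean was 2.14 to 2.153 in the 3 MDL-800 libraries and 2.086 to 2.117 in the 4 control libraries, with an exact permutation p of 0.0286, the smallest that 35 assignments can give (0.99 after adjustment over 52 lists). Their fry p was 0.0318 (0.828 after adjustment). The median of glycolysis genes was 0.04 over 19 members (adjusted p = 0.477). Neutrophil markers had a median of -0.62, with 8 of 8 members below 0 (adjusted p = 0.0786). Their log2 mean was 4.437 in control 2. In the other control libraries it was 1.754 to 2.182, within the MDL-800 range of 1.009 to 2.868. For hepatocyte markers the median was -0.12 and the mean 0.04, which differ in sign.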

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

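The tests of control 4, of the Y-linked libraries, of the permuted list mean and of control 3, and the count of splits for genes, were chosen after the result was seen.

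In 6 of 96 values tested within the control group, 1 library stood apart from the other 3, and chance gives about 1 in 20. The gap divided by the range was 0.949 for Ifitm2 and 0.948 for Clec4g in control 4, 0.866 for Cyp46a1 and 0.943 for Mup7 in control 1, and 0.885 for Alg8 and 0.869 for Sdhd in control 2.

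No gene passed the limma test, and 553 had an unadjusted p under 0.05. With a count of 0, all 35 of 35 splits of the 7 libraries give as many by construction, so the splits say nothing here, and the highest other split gave 5 genes, with control 1 and MDL-800 2 in the same group. A spread between the libraries with and without Y-linked reads stays open: 0 genes passed with a term for it, while the count at an unadjusted p under 0.05 was 828 with the term and 553 without. Limited power may contribute, since 36.7% of simulated 2-fold changes were called, but 75.2% of 4-fold changes were called at the same sample size. Each simulated set mixed 1.5-fold, 2-fold and 4-fold changes under 1 adjustment, so these shares hold for that mix. Sets with only small changes were not simulated. A small or absent effect of MDL-800 on most transcripts stays open.

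The number of lists that passed camera, 12, was reached by 31 of the 35 splits, and the highest other split gave 27, with control 1 and MDL-800 2 together. Chance can therefore not be excluded for the number of lists, and the preset correlation called many lists for groupings that follow no treatment.

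The acute phase list lay lower in MDL-800 libraries. Control 4 alone was argued against, since the list median was -0.447 without it. That was the weakest median over the alternatives, against -0.657 with all libraries, so control 4 carried part of the difference. The unequal share of libraries with Y-linked reads was also argued against, since the median was -0.632 within the 5 Y-negative libraries. A chance split of the libraries stays open: 2 of 35 assignments gave as large a difference of list means, and the highest other difference was 0.929. An effect of MDL-800 on acute phase transcripts may be followed up as a hypothesis.

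Control 3 had 0 reads of Xist and of the 4 Y-linked genes. Too few reads were argued against, since 12701 Xist reads would be present at the lowest level of the 4 Xist-positive libraries. A male library that lost its Y-linked reads was argued against by male-biased genes, on whose mean control 3 stood at 0.0308 on a scale from 0 for Xist-positive to 1 for Y-positive libraries, and by female-biased genes (-0.124), while the major urinary proteins, near-identical copies, went the other way (0.77). A single X chromosome could not be decided: over 10 genes that escape X inactivation, control 3 had a median of -0.2 (log2) against the Xist-positive libraries, between those and the Y-positive libraries (-0.379 and -0.248). The genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x had been seen before the list was written. Over the other 6 genes the medians were -0.2 in control 3, -0.216 in control 1 and -0.279 in MDL-800 2. In the Xist-positive libraries they ran from -0.12 to 0.117.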

How the results depend on the processing

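The Y-linked, voom, denominator and permutation alternatives were chosen after seeing the data. The gene count was 0 under each alternative except when a library was left out, where it ranged from 0 to 1. The count at an unadjusted p under 0.05, 553 of 11394 genes, was 1083 of 26975 without a filter, 305 of 5900 at a mean of at least 5 FPKM and 192 with the replicate block. The list count ranged from 12 to 19 when a library was left out, was 16 with the replicate block, and was 0 with an estimated correlation, 0 with fry and 0 with permutation of list means, methods whose construction allows for correlation between genes. The acute phase, fatty acid oxidation and TCA cycle lists passed camera under all 7 leave-one-out settings and all 12 other settings that kept the preset correlation. These settings reuse the same libraries and the preset correlation, with which 31 of 35 splits called as many lists. They are therefore no independent check of the 3 lists. Libraries with the same number did not deviate together (correlations across genes of -0.587, -0.553 and 0.0565). Control 1 and MDL-800 2, the libraries with Y-linked reads, did (0.771), and they carry different numbers. The difference tied to Y-linked reads was not removed first, so this check cannot exclude pairing. Numbers were not taken as pairs because the labels do not say that they mark a shared litter or batch. With the replicate block 0 genes passed, and the calls of NF-kB targets, endothelial markers and antigen presentation ended. Control 4 has no partner, so the block also removed it from the comparison. The same calls ended when only control 4 was left out, so their loss cannot be put down to the block.

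Sirt6 expression ranged from -0.14 to 0.0047 (log2) when a library was left out and was 0.011 in the Y-negative libraries. Values that changed sign, none past the threshold, were as follows, and the cause was not tested. Under median scaling Sirt1 was -0.028 and Sirt4 -0.011. With the replicate block, which also removed control 4 from the comparison, Sirt1 was -0.031, Eng -0.035, Mup3 -0.38 and Mup7 -0.49. With array weights Sirt1 was -0.038, Sirt4 -0.036, Mup3 -0.33, Mup7 -1.20, NF-kB targets 0.076 and antigen presentation 0.013. With the Y-linked term Sirt1 was -0.0085, Sirt4 -0.0013, Mup3 -0.12 and Mup7 -0.39. In the Y-negative libraries Sirt1 was -0.026, Sirt2 0.016, Jund 0.0085, Mup7 -0.23 and antigen presentation 0.055. Leaving out a library gave -0.035 to 0.40 for Eng, -1.74 to 0.10 for Igkc, -1.11 to 1.42 for Mup3, -3.21 to 3.55 for Mup7, -0.60 to 0.012 for Psmb8, -0.49 to 0.0068 for Psmb9, -0.071 to 0.090 for Sirt1, -0.10 to 0.023 for Sirt2, -0.072 to 0.12 for Sirt4, -0.38 to 0.017 for Tap2, -0.37 to 0.11 for NF-kB targets and -0.53 to 0.19 for antigen presentation. Of 1480 values of 79 other named genes under alternatives, 1440 kept their direction and side of the threshold. None of these genes passed in the main test, and many were named for a small p in the same libraries. The count is therefore no independent check of their changes. Depth limits Gm22200, which rested on at most 4 reads.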

Other observations

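The libraries with Y-linked reads, control 1 and MDL-800 2, differed from the other 5 libraries in genes known to differ between male and female liver. With a limma term for these libraries beside treatment, 276 genes passed, 151 higher and 125 lower in the Y-positive libraries. These sets of libraries were defined from the data and are not groups of the study. Of 21 male-biased liver genes, 16 were higher and 0 lower, and of 22 female-biased genes, 16 were lower and 0 higher. Hsd3b5, a male-biased steroid enzyme, was at 186.1 and 100.9 FPKM as deposited in control 1 and MDL-800 2, and at most 0.131 FPKM in the other libraries. Cyp2a4, a female-biased cytochrome P450, was at 315.6 to 1125 FPKM in the Y-negative libraries and at most 0.111 FPKM in the others, as deposited. No gene passed a limma test of whether the difference between MDL-800 and control depended on these libraries (lowest adjusted p = 0.183, 253 genes at an unadjusted p under 0.05). That test has 1 Y-positive library per group, each assumed to vary like the others, so it does not show that the difference was alike in both.

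Control 2 held the highest values of the cytokine genes Il1b and Ccl3 and of neutrophil markers. Il1b, the interleukin-1 beta gene, was at 18.1 FPKM there and at most 4.61 FPKM in the other 6 libraries, and Ccl3 at 10.9 FPKM against at most 2.31 FPKM, as deposited. The mean of neutrophil markers on the log2 scale was 4.44 in control 2 and at most 2.87 elsewhere. Mt1, a metallothionein, was at 296.5 to 657.7 FPKM in control 2, control 3 and control 4 and at 106.6 and 114.8 FPKM in MDL-800 1 and MDL-800 3, as deposited. The libraries with Y-linked reads had 15.8 FPKM of Mt1 in control 1 and 17.3 FPKM in MDL-800 2. Il1b, Ccl3 and Mt1 were chosen after their values were seen, and none passed limma between MDL-800 and control (adjusted p = 0.951, 0.962 and 0.95, log2 fold changes of -0.41, -0.40 and -1.77). Mt1 is a member of the acute phase list, and Il1b and Ccl3 of the NF-kB list, so they are also part of those list results. With the limma term for Y-linked reads, Mt1 was lower in the Y-positive libraries (log2 difference -3.79, adjusted p = 0.0278). Whether control 2 stood apart from the other libraries in these genes was not tested.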
